A study of Rattus norvegicus with 6 samples.

How the data were processed

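RNA from 6 cultures of fetal rat lung type II epithelial cells, 3 strained and 3 control, was hybridised to 6 Affymetrix rat E230A arrays, 1 array per culture with a single biotin label, per the labels' protocols. The deposited table holds, for each array, an intensity per probe set on a linear scale, the signal made with MAS5 version 5.0 per the submitters' processing notes. Before deposit the authors had scaled the arrays, since the 2% trimmed mean of every deposited column lay between 500.129 and 500.148. Signals ran from 0.1 to 29078.5. Probe-level values and detection calls were not used here, so signal over background was judged only through the mean signal. The labels state that RNA was extracted with TRIzol and purified on a column. Text files that describe each array run gave the run day, chip lot, fluidics module and scan order, and were used only to find batches.

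Pair 1 was run on one day and pairs 2 and 3 on another. Pairs 1 and 2 shared a chip lot, and pair 3 had a different one. The pair is the replicate number in the sample titles, and the series' design text states that each pair came from its own litter. The numbers were set against the values: deviations from the group means of same-numbered control and strained arrays correlated across probe sets at 0.51, 0.47 and 0.43, while the other 6 combinations lay between -0.35 and -0.12. Same-numbered arrays also shared run day and chip lot, so this cannot tell a shared litter from a shared batch. Deviations cancel within a group, which favours negative values for the other combinations. No 2 arrays held the same values, with Pearson correlations of log2 signals from 0.938 to 0.979 across probe sets. Each pair is the comparison of 2 cultures from 1 litter, and differences between litters are removed by the pair term. Probe set p-values, SEs and confidence intervals rest on variances mostly borrowed from other probe sets, at 9 of 11 degrees of freedom. How the difference of the same probe set varied from pair to pair thus enters only in small part. The p-values of gene lists rest also on the spread across genes.

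Signals were scaled to a trimmed mean of 500 with 2% trimmed at each end, which left them nearly as deposited, and transformed as log2(signal + 16). A log2 difference on this scale understates changes of dim probe sets. The 57 control probe sets were left out, and the 40% of the other 15866 probe sets with the lowest mean log2 value over all arrays were dropped, which corresponds to a signal of about 115.5 and left 9519 probe sets. Gene symbols came from the platform annotation and were looked up by gene ID in a RefSeq table. Of the 15866 probe sets, 12783 had 1 symbol, 312 had several and 2771 had none. The gene IDs of 12748 were found in the RefSeq table, and no symbol changed. No gene is named from a probe set with several symbols.

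The model was fitted in limma 3.58.1 under R 4.3.3, with the litter pair and the group as terms, moderated variances with a trend on intensity, and Benjamini-Hochberg adjustment over all 9519 probe sets at 0.05. A second count took probe sets that differed by at least 1.5-fold in the same direction in all 3 pairs. Gene lists were tested on 7163 genes, each represented by the brightest of its probe sets, which for Trib3 is not the probe set with the smallest p. The test was limma's camera with a preset correlation of 0.01 between genes. Camera with a correlation estimated for each list, which has few degrees of freedom with 3 pairs, and the rotation test fry were run beside it. There were 23 functional lists and 9 cell type lists, and the 28 with at least 5 measured members were tested. Each list's members were also adjusted over the list alone. For its median, each list was compared with 10000 lists of the same size matched on mean signal.

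The genes to be named were fixed by rule before the data were examined, as were the lists, the tests of strain and the alternative settings. In each direction, up to 15 called genes with the largest log2 difference that moved the same way in all 3 pairs were named, and where fewer than 10 passed, genes with at least 1.5-fold and the same direction in all pairs filled the list to 10. Up to 4 members of each list with the smallest p could be named, with any member that passed over its list alone. A fixed set of lung and cell type genes, among them the surfactant protein genes, Aqp5, Pdpn, Scnn1a, Col1a1, Ptprc and Pecam1, was always to be named. Pck2, Tm7sf2, Sqstm1, Myadm, Fads3, Lgals3, Sars1 and Gars1 fall outside this rule and were named after their values were seen, because they complete the called genes.

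The scripts were tested on 20 simulated data sets built from the real means, litter effects and moderated residual spread, each with 200 changed probe sets among 9519 tested on average for the strain comparison. Their noise was independent between probe sets and its variance already leaned to the trend on intensity that the fit assumes. The rates therefore hold for data that follow the model of the fit. The paired fit recovered 54.7% of probe sets changed by 1.5-fold, 90.5% of those changed by 2-fold and 99.6% of those changed by 3-fold, and 7.04% of calls were false. In the same data, camera called all 10 lists of 20 genes raised by 0.3 on the log2 scale and on average 0.6 of 100 untouched lists, whose genes varied independently there. Alternatives changed the pair block, the scaling, the offset, the dim filter, the variance model, the threshold, the correlation between genes and the probe set per gene, and left out each pair, or each array in a fit with no block. With a random block or robust variances, the list test took log2 differences over their SE, through limma's cameraPR in place of camera. In the synthetase test, the permutation was first sampled and then, after its result had been seen, replaced by all arrangements of the genes, which lowered p slightly. Herpud1 was added to the endoplasmic reticulum set after a first run, so that the amino acid and endoplasmic reticulum sets together make up the whole list.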

Results

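Gene expression was measured in epithelial cells isolated from fetal rat lung at embryonic day 19. These are the precursors of alveolar type II cells, which make pulmonary surfactant. They were grown on flexible silastic membranes that carried a coat of collagen 1, and were either stretched for 16 h or kept unstretched for the same time. In each hour the stretched cultures received 5% cyclic strain at 60 cycles per min for 15 min and 2.5% continuous distension for the other 45 min, a regime meant to imitate the mechanical forces acting on the lung before birth. There were 3 control and 3 strained samples, arranged as 3 pairs with a different litter for each pair, and each sample was hybridised to 1 array. Every array gave a signal for 15923 probe sets, with medians from 161.7 to 199.0. The replicates are cultures from different litters, and the number of arrays limits the precision of every value.

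The comparison of strained with control cells asked which transcripts respond to mechanical force. Trib3, a pseudokinase induced by ATF4, rose from a mean signal of 238 ± 198 (SD, n = 3) to 1023 ± 761 (n = 3), a log2 difference of 2.10 ± 0.15 (SE, adjusted p = 0.00028). Another called probe set of Trib3 gave 0.96 ± 0.17, and the remaining probe set gave 1.12 ± 0.21 with an adjusted p of 0.057. Herpud1, a membrane protein of the endoplasmic reticulum that takes part in protein degradation, rose from 547 ± 51.1 to 1711 ± 529 (log2 difference 1.58 ± 0.14, adjusted p = 0.0014). At the lower end, Fbn1, which encodes the microfibril protein fibrillin 1, fell from 4161 ± 513 to 2455 ± 427, with a log2 difference of -0.76 ± 0.10 (adjusted p = 0.0099).

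In all, 31 of 9519 tested probe sets passed an adjusted p of 0.05 in limma with the litter pair as a block, 26 higher and 5 lower under strain. Each of the 31 moved the same way in all 3 pairs, which selection by this fit favours. The higher ones belong to 24 genes. The lower ones are Fbn1, Igfbp2 and 3 probe sets annotated to several genes, which are not named. Over all tested probe sets the differences within pairs were hardly alike. They correlated at 0.275 between pairs 1 and 2, -0.049 between pairs 1 and 3, and 0.078 between pairs 2 and 3. At an unadjusted p of 0.05, 899 probe sets passed, where 476 would be the mean count by chance, and 716 passed with the labels of pair 3 turned. Correlation between probe sets widens the spread around that mean. With no pair block in the fit the count of calls was 0, with 200 probe sets under an unadjusted p of 0.05, so every call rests on the comparison within litters. Leaving out pair 2 left 9 calls and leaving out pair 1 gave 52, which is also the count within the second run day, since pairs 2 and 3 were run together on a day after pair 1. Pair 1 alone made up the first run day and allows no test, and with run day in place of the pair as the block 1 probe set passed. The count was 5 with no filter on dim probe sets, and 1 without the trend of the variance on intensity.

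Several called genes encode amino acid transporters. Slc7a5 and Slc3a2, the light and heavy chains of a carrier for large neutral amino acids, rose by log2 differences of 1.09 ± 0.15 and 0.89 ± 0.10 (adjusted p = 0.015 and 0.0040). The cationic amino acid transporters Slc7a3 and Slc7a1 rose by 1.00 ± 0.14 and 0.82 ± 0.11 (adjusted p of 0.015 for each), and the second probe set of Slc7a1 was also called, at 0.78 ± 0.14. Enzymes of amino acid synthesis rose as well. The asparagine synthetase gene Asns rose by 0.93 ± 0.11 (adjusted p = 0.0072), and Phgdh and Psat1, of the serine pathway, rose by 0.82 ± 0.12 and 0.79 ± 0.11 (adjusted p of 0.015 for each). Cars1, Sars1 and Gars1, which charge tRNA with cysteine, serine and glycine, rose by 0.82 ± 0.13, 0.61 ± 0.10 and 0.53 ± 0.09 (adjusted p from 0.022 to 0.039). The other 2 tested probe sets of Cars1 gave 0.40 and 0.44 and were not called. The transcription factor genes Atf4 and Atf5 rose by 0.69 ± 0.08 and 0.95 ± 0.15, and Chac1, a glutathione-degrading enzyme induced by ATF4, rose by 0.98 ± 0.11 (n = 3 pairs throughout).

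The other called genes with higher signal in strained cells had several known roles. Hmox1, the heme oxygenase induced by oxidative stress, rose by a log2 difference of 0.89 ± 0.13, and Sqstm1, an autophagy receptor, by 0.60 ± 0.10. Eif4ebp1, a repressor of cap-dependent translation, rose by 0.77 ± 0.12, and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, by 0.75 ± 0.12. Tm7sf2, a sterol reductase of cholesterol synthesis, rose by 0.65 ± 0.10, and Fads3, a member of the fatty acid desaturase family, by 0.48 ± 0.08. Cmtm3 rose by 1.00 ± 0.14, Myadm by 0.60 ± 0.09 and the galectin gene Lgals3 by 0.46 ± 0.07. Adjusted p-values of these 9 genes lay between 0.015 and 0.029.

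**Figure D1:**
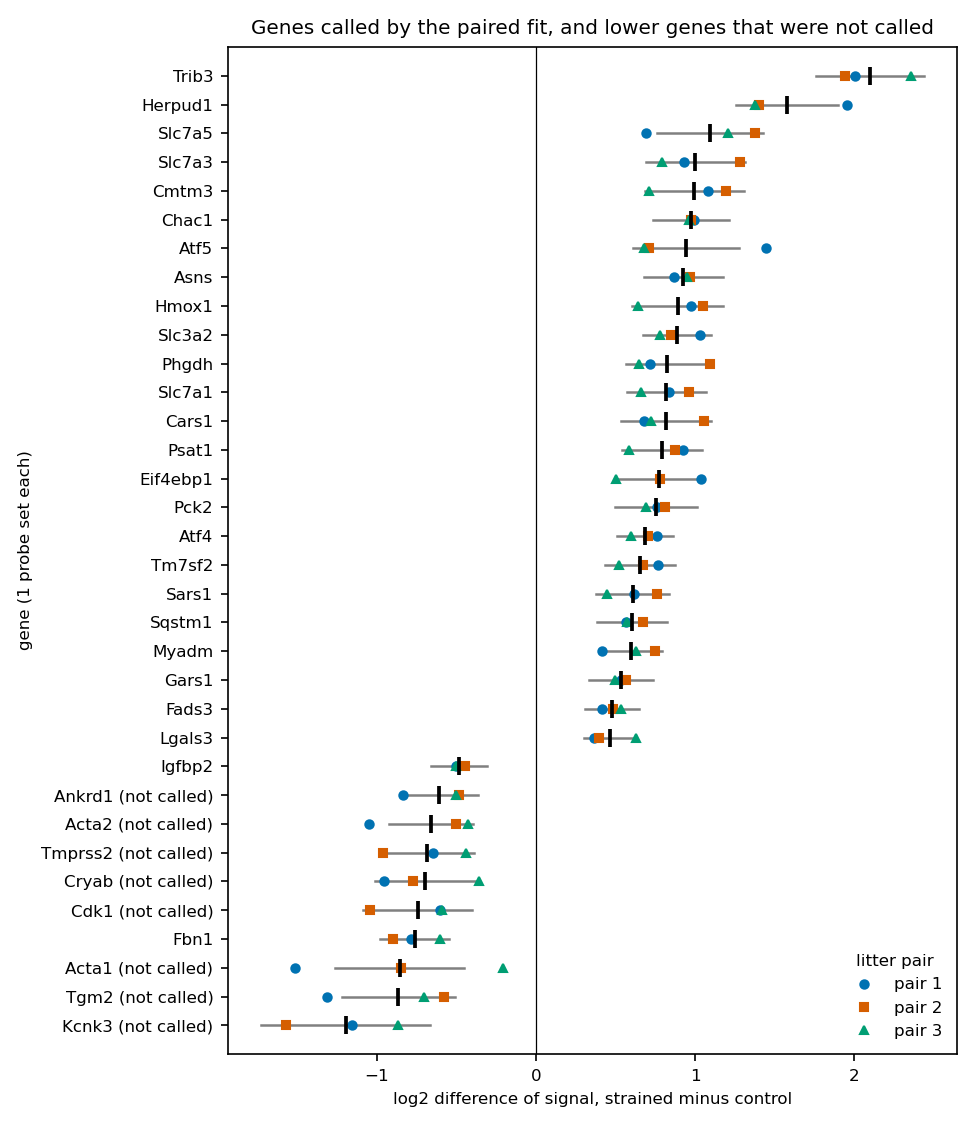
Log2 difference of signal, strained minus control, for the 26 called genes with a single gene symbol and for 8 lower genes that did not pass. Points are the 3 litter pairs, black ticks the fitted differences and grey lines their 95% confidence intervals. These intervals rest mostly on variances borrowed from other probe sets. All 3 points of each gene lie on the same side of 0, with Trib3 farthest to the right at 2.10.

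Beside Fbn1, the only called lower gene with a single symbol was Igfbp2, an insulin-like growth factor binding protein, at -0.48 ± 0.08 (adjusted p = 0.035). The second probe set of Fbn1 gave -0.62 ± 0.12 and did not pass (adjusted p = 0.083). Of the genes that were lower by at least 1.5-fold on average, and by any amount in each of the 3 pairs, but missed the threshold, the 8 with the smallest p are given here. Acta2, the smooth muscle actin gene, and Ankrd1, a target of the mechanosensitive factors YAP and TEAD, came closest, at -0.66 ± 0.12 and -0.61 ± 0.11 (adjusted p of 0.051 for each). Tgm2, a transglutaminase that crosslinks matrix proteins, was at -0.87 ± 0.16 (adjusted p = 0.064). Tmprss2, an epithelial serine protease, was at -0.68 ± 0.13 (adjusted p = 0.079), but its second probe set was at -0.12 ± 0.15. The potassium channel gene Kcnk3 was at -1.20 ± 0.24 (adjusted p = 0.090) on a dim probe set, and its other probe set was at 0.04 ± 0.24. Cryab, Cdk1 and the skeletal actin gene Acta1 were at -0.70 ± 0.14, -0.75 ± 0.16 and -0.86 ± 0.18, with adjusted p-values from 0.10 to 0.12.

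Counting by size alone, 27 probe sets differed by at least 1.5-fold in the same direction in all 3 pairs, 20 higher and 7 lower in strained cells. Of these, 20 were also called by limma. Turning the labels of pair 1, 2 or 3 gave totals of 3, 2 and 9. At a 2-fold threshold 4 probe sets were left, and without the dim filter there were 101. With only 2 pairs to satisfy, the count was 84 without pair 1, 63 without pair 2 and 141 without pair 3.

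Of 28 gene lists with at least 5 measured members, 11 passed an adjusted p of 0.05 in limma's camera test with a preset correlation of 0.01, 6 upward and 5 downward. The strongest was the list of amino acid and endoplasmic reticulum stress genes, which rose with a median log2 difference of 0.33 (camera adjusted p = 6.61e-13; adjusted p = 0.387 with an estimated correlation, the lowest of all lists). Of its 26 measured members 10 were called higher, 13 were higher and 1 lower when adjusted over the list alone, and 15 were higher in all 3 pairs, while 8 were negative. Among the members added over the list alone were Ddit3, which encodes the stress transcription factor CHOP, at 0.77 ± 0.17, the lipoprotein receptor gene Vldlr at 0.86 ± 0.20 and the serine hydroxymethyltransferase gene Shmt2 at 0.42 ± 0.10. The lower member was Creld2, which encodes a protein of the endoplasmic reticulum, at -0.46 ± 0.12. The median was 0.52 in pair 1, and within the second run day the list had a median of 0.33 (camera adjusted p = 9.78e-13). With a correlation estimated from the data none of the 11 calls held. The estimate lay below the preset 0.01 for the amino acid (0.0012), cholesterol (-4.73e-05), fatty acid (-0.032) and EGF receptor (-0.062) lists. A stronger correlation therefore cannot account for the loss of these calls. For the other called lists the estimate lay above the preset. That form of the test has few degrees of freedom with 3 pairs. The rotation test fry, which asks whether a list moved on balance, called no list either, with a lowest adjusted p of 0.118. Its mixed form, which asks whether members changed in either direction and does not compare them with other genes, passed for 10 of the 28 lists, 4 of them among the 11. Its adjusted p was 0.0057 for ion and water transport, 0.0093 for immediate early genes and 0.020 for each of the amino acid, YAP and TEAD, and hypoxia lists. As many lists, 11, passed camera when the labels of pair 3 were turned, and 5 passed without pair 1. Among lists matched on mean signal, the medians of the called fatty acid and growth factor lists lay at percentiles 94.64 and 3.99. The other called lists lay at 98.99 or above or at 0.29 or below. Some lists that did not pass were also far out: YAP and TEAD targets at 0.17, oxidative phosphorylation at 0.25, surfactant genes at 2.43 and the glucocorticoid response at 99.83.

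The list of cell cycle genes fell, with a median log2 difference of -0.41 over 26 members (camera adjusted p = 2.16e-07; adjusted p = 0.487 with an estimated correlation). No member was called among all probe sets, 5 were lower when adjusted over the list alone, and 15 were lower in all 3 pairs. Beside the mitotic kinase Cdk1, they included Cdc20, an activator of the anaphase-promoting complex, at -0.52 ± 0.15, the replication helicase gene Mcm5 at -0.54 ± 0.16 and the ubiquitin-conjugating enzyme gene Ube2c at -0.51 ± 0.16. The median was -0.14 in pair 1, and within the second run day it was -0.43 (camera adjusted p = 3.23e-08). In the same cultures smooth muscle and myofibroblast markers had a median of -0.35 (camera adjusted p = 0.0055; adjusted p = 0.489 with an estimated correlation) and a pair 3 median of -0.02. Leukocyte markers had a median of -0.23 (camera adjusted p = 0.048; adjusted p = 0.592 with an estimated correlation) and a pair 3 median of 0.12.

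Cholesterol synthesis genes rose, with a median log2 difference of 0.18 over 18 members, 17 of them positive (camera adjusted p = 2.14e-06; adjusted p = 0.426 with an estimated correlation). No member was called among all probe sets, and Msmo1 at 0.39 ± 0.08 and Cyp51 at 0.41 ± 0.09, both of the demethylation steps after lanosterol, passed over the list alone. The other probe set of Cyp51 was at 0.25 ± 0.13. The list of fatty acid and phospholipid synthesis had a median of 0.07 over 20 members (camera adjusted p = 0.023; adjusted p = 0.487 with an estimated correlation). None of its members passed, over all probe sets or over the list alone. Agpat2, an acyltransferase of phospholipid synthesis, was at 0.43 ± 0.13 and the desaturase gene Fads2 at 0.32 ± 0.11. Within the second run day the cholesterol list had a median of 0.15 (camera adjusted p = 0.0011) and the fatty acid list did not pass (adjusted p = 0.142). Of the 9 fits that left out a pair or an array, the cholesterol list passed in 9 and the fatty acid list in 3, with an adjusted p of up to 0.275. In pairs 1, 2 and 3 the medians were 0.35, 0.13 and 0.15 for the cholesterol list and 0.20, -0.02 and 0.11 for the fatty acid list.

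Immediate early genes, the fast transcriptional targets of growth factor and stress signals, rose with a median log2 difference of 0.12 over 19 members (camera adjusted p = 0.0034; adjusted p = 0.487 with an estimated correlation). No member was called over all probe sets. Ier2, Fosl1 and Atf3 passed over the list alone, at 0.52 ± 0.13, 0.61 ± 0.17 and 0.47 ± 0.14. Within the second run day the median was 0.17 (camera adjusted p = 0.016), and in pair 1 it was -0.02. The list passed in 6 of the 9 fits that left out a pair or an array, with an adjusted p of up to 0.151. The antioxidant list rose with a median of 0.10 over 23 members (camera adjusted p = 0.0055; adjusted p = 0.489 with an estimated correlation). Hmox1 was called, and Nqo1, a quinone reductase, passed over the list alone at 0.35 ± 0.09. The list of EGF receptor ligands and ERK feedback genes had a median of 0.11 over 16 members and a camera adjusted p of 0.048 (adjusted p = 0.487 with an estimated correlation). None of its members passed over all probe sets or over the list alone. Dusp6, an ERK phosphatase, was at 0.54 ± 0.16, with 0.99 ± 0.19 and 0.70 ± 0.21 on its other probe sets, which were not called either. Errfi1, an inhibitor of the EGF receptor, was at 0.61 ± 0.20, with a pair 3 difference of -0.13. Neither the antioxidant nor the EGF receptor list passed within the second run day (adjusted p of 0.264 and 0.142), and their medians in pair 1 were 0.22 and 0.02. Of the 9 fits with a pair or an array left out, the antioxidant list passed in 6 and the EGF receptor list in 2, and the latter also missed the threshold in 4 of 13 other settings with all pairs.

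The list of extracellular matrix and basement membrane genes fell, with a median log2 difference of -0.10 over 25 members, 20 of them negative (camera adjusted p = 0.0049; adjusted p = 0.487 with an estimated correlation). No member was called over all probe sets, and Tgm2 passed over the list alone. The laminin chain genes Lamc1 and Lama3 were at -0.28 ± 0.09 and -0.39 ± 0.13. Within the second run day the median was -0.14 (camera adjusted p = 0.0041), against -0.22 in pair 1. When an array was left out of the fit with no pair block, the list failed in 3 of 6 cases, with an adjusted p of up to 0.368. The smooth muscle and myofibroblast markers, of cells that make matrix, had a median of -0.35 (camera adjusted p = 0.0055; adjusted p = 0.489 with an estimated correlation). Lung growth factors and morphogens fell, with a median of -0.09 over 23 members (camera adjusted p = 0.048; adjusted p = 0.489 with an estimated correlation). None was called over all probe sets. Bmp4, a morphogen of airway branching, passed over the list alone at -0.45 ± 0.11, and Tgfb3 was at -0.43 ± 0.16. Within the second run day this list did not pass (adjusted p = 0.382), and its medians in pairs 1, 2 and 3 were -0.19, -0.29 and 0.01. It passed in 7 of 13 other settings with all pairs and in 1 of 9 fits that left out a pair or an array, and failed with no pair block (adjusted p = 0.125) and without pair 2 (adjusted p = 0.162).

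Markers of other cell types that a type II isolate could hold moved in part. Smooth muscle and myofibroblast markers fell, with a median log2 difference of -0.35 over 9 members and Acta2 past the threshold over the list alone (camera adjusted p = 0.0055; adjusted p = 0.489 with an estimated correlation). Leukocyte markers had a median of -0.23 over 12 members and fell (camera adjusted p = 0.048; adjusted p = 0.592 with an estimated correlation), though none passed singly. Cd74, of antigen presentation, was at -0.29 ± 0.18 and the macrophage marker Cd68 at -0.28 ± 0.21. Neither list passed within the second run day (adjusted p of 0.197 and 0.383). The leukocyte list passed in only 5 of 13 other settings with all pairs and in 2 of 9 that left out a pair or an array, and failed under quantile normalization (adjusted p = 0.086), cyclic loess (adjusted p = 0.064) and without pair 2 (adjusted p = 0.416). In pairs 1, 2 and 3 the medians were -0.47, -0.38 and -0.02 for the smooth muscle list and -0.40, -0.35 and 0.12 for the leukocyte list. The smooth muscle list failed in 3 of 9 fits that left out a pair or an array, with an adjusted p of up to 0.372. Fibroblast markers had a median of -0.02 over 13 members and did not pass (camera adjusted p = 0.155). Beside Fbn1, Col1a2 passed over the list alone at -0.61 ± 0.15, with -0.20 on its other probe set, and Col5a2 was at -0.34 ± 0.14. Col1a1 was at 0.18 ± 0.09, with -0.05 ± 0.11 on its other probe set. The median of the fibroblast list changed sign under quantile and cyclic loess normalization. Mesothelial and neuroendocrine markers did not pass, with medians of -0.10 over 6 and -0.10 over 5 members (camera adjusted p of 0.371 and 0.925). Endothelial, erythroid, club cell and ciliated cell lists had 4, 3, 4 and 3 measured members and were not tested. The leukocyte gene Ptprc and the endothelial gene Pecam1 lay under the dim filter, with mean signals of at most 28.7.

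Surfactant and type II differentiation genes went both ways and did not pass as a list, with a median log2 difference of -0.09 over 14 members (camera adjusted p = 0.196). Over the list alone 4 members passed, and over all probe sets none did. Sftpc, the surfactant protein C gene, was higher in all 3 pairs at 0.57 ± 0.12, from 1232 ± 124 to 1872 ± 475. The phosphate transporter gene Slc34a2, the mucin gene Muc1 and the lysozyme gene Lyz2 were lower, at -0.77 ± 0.20, -0.30 ± 0.09 and -0.41 ± 0.13. Lyz2 was also a member of the leukocyte list. Sftpb, Sftpd and the lamellar body transporter gene Abca3 were at -0.23 ± 0.16, -0.20 ± 0.11 and -0.16 ± 0.12 and did not pass either test. Both probe sets of Sftpa1 lay under the dim filter, with mean signals from 70.4 to 103. Alveolar type I genes did not pass as a list (median -0.02 over 15 members, camera adjusted p = 0.319). Igfbp2 was called, and Cryab and Hopx, the latter at -0.35 ± 0.11, passed over the list alone, whereas the type I markers Aqp5 and Pdpn were at -0.26 ± 0.21 and -0.04 ± 0.08.

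Ion and water transport genes did not pass as a list (median log2 difference -0.07 over 17 members, camera adjusted p = 0.196), and 4 of them passed over the list alone in opposite directions. The 3 subunit genes of the epithelial sodium channel were among these. Scnn1a, the alpha subunit, was higher in all pairs at 0.64 ± 0.12, with 0.89 ± 0.21 on its second probe set. Scnn1g and Scnn1b, the gamma and beta subunits, were lower in all pairs at -0.51 ± 0.12 and -0.44 ± 0.12. The water channel gene Aqp4 was at -0.77 ± 0.19, with -0.01 on its second probe set. None of these passed over all probe sets, and Scnn1a came closest, with an adjusted p of 0.071.

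The lists that respond to mechanical tension in other cells did not pass. YAP and TEAD targets had a median log2 difference of -0.14 over 15 members (camera adjusted p = 0.196). Over the list alone, Ankrd1 and Dlc1 were lower, at -0.61 ± 0.11 and -0.48 ± 0.14, and Ccn1 was higher at 0.48 ± 0.14, as was Ajuba at 0.27 ± 0.09. Actin cytoskeleton and SRF targets had a median of -0.01 over 24 members (camera adjusted p = 0.919), where camera gave the upward direction against a negative median and mean. Cell junction and integrin genes had a median of 0.05 over 19 members (camera adjusted p = 0.197).

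Other lists fixed for this tissue and treatment also did not pass. Their median log2 differences and camera adjusted p-values were 0.17 and 0.058 for the glucocorticoid response, -0.07 and 0.170 for oxidative phosphorylation, and -0.05 and 0.197 for inflammatory mediators. They were -0.06 and 0.261 for the interferon response, 0.05 and 0.261 for hypoxia and glycolysis, and 0.01 and 0.275 for p53 targets and apoptosis. For the heat shock response they were 0.07 and 0.317, and for cyclic AMP and prostaglandin signalling 0.06 and 0.410. In the heat shock list, Cryab was lower and the small heat shock protein gene Hspb8 higher over the list alone, the latter at 0.55 ± 0.15.

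**Figure D2:**
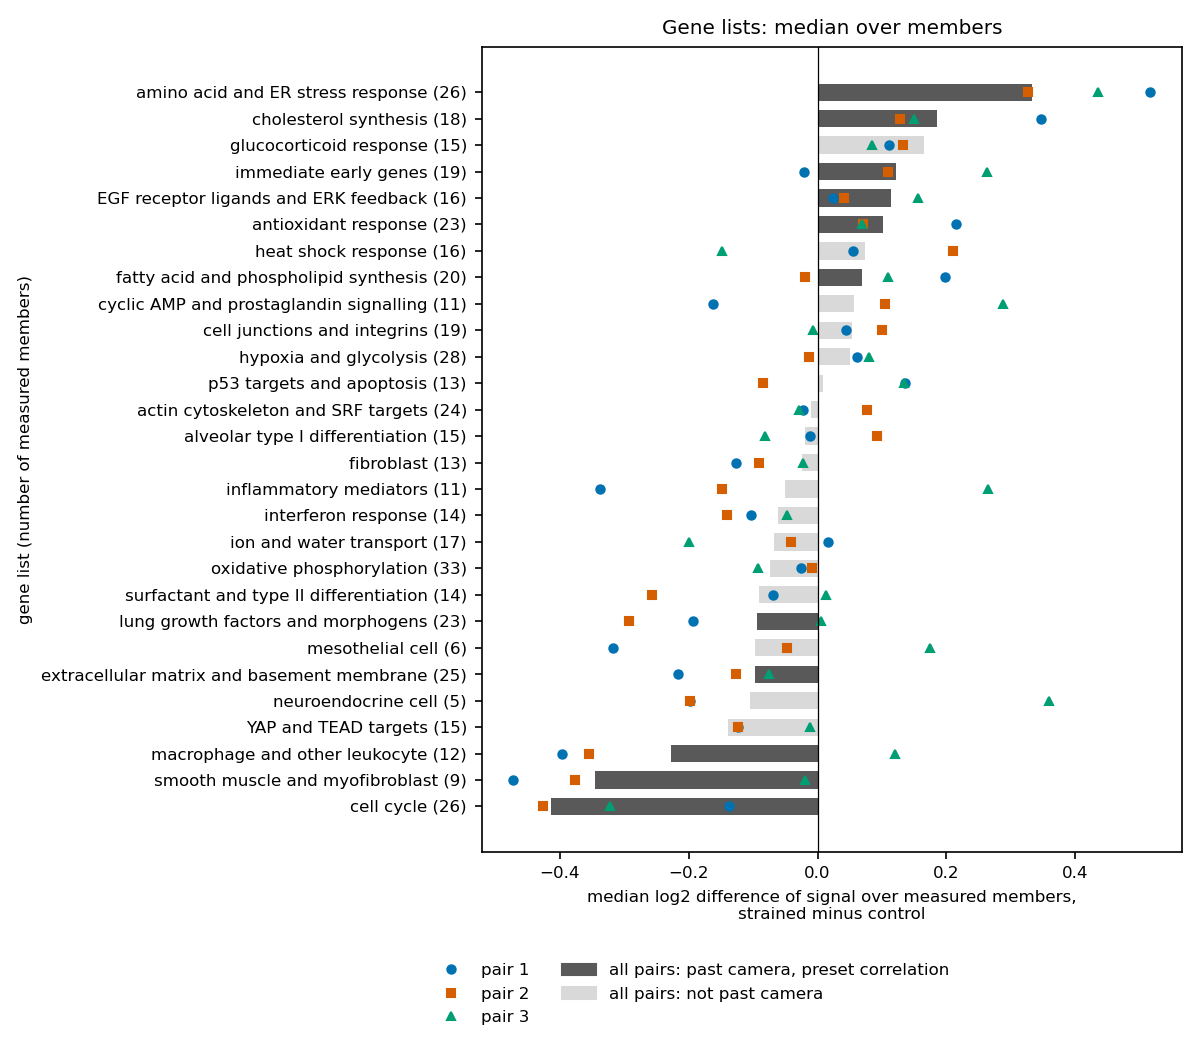
Median log2 difference of signal over the measured members of each gene list, strained minus control, with the number of members in brackets. Bars are the fit over all pairs, dark where the list passed camera with the preset correlation, and points are the medians of the 3 litter pairs. The amino acid list, at 0.33, and the cell cycle list, at -0.41, lie at the ends, and among the called lists 1 pair lies on the other side of 0 for the immediate early, fatty acid, leukocyte and growth factor lists.

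The ratio of 3' to 5' signal, a sign of RNA integrity, did not follow the groups. For Gapdh the ratio lay between 1.41 and 1.56 in controls 1 and 2 and was 1.81 in control 3, against 1.47, 1.73 and 1.79 in the strained samples. For beta-actin it lay between 1.47 and 1.62 in controls and between 1.30 and 1.66 in strained samples. The log2 difference within pairs was negative in 1 of 3 pairs for Gapdh and in 2 of 3 for beta-actin. In every pair the control array was washed in the lower-numbered fluidics module and scanned 10 or 11 min before its strained partner, so the effects of this order and of strain could not be separated.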

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

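The search for signals outside the tested probe sets was set up after the values had been seen. Of the 57 control probe sets, 26 lay above the dim filter, and 1 of them was at least 1.5-fold higher in the strained array of every pair. It represents rat 5S ribosomal RNA. Its signal was 171.0 in the control and 297.6 in the strained sample of pair 1, 135.8 and 236.4 in pair 2, and 102.2 and 171.8 in pair 3, so the lowest ratio was 1.68. None of the 26 was lower by as much in every pair.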

How the results depend on the processing

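Against 31 called probe sets, the count was 0 with no pair block, 17 with the pair as a random block, 16 of them shared, 5 with no dim filter, 1 without the variance trend, 1 with run day as the block, and 47 at an adjusted p of 0.10. It lay between 24 and 35 under the scalings, offsets, stricter filter and robust variances, and between 0 and 52 when a pair, or an array in the fit with no block, was left out. The filter-free fit tested 15866 probe sets; for the other losses the cause was not tested. All 26 called genes kept their call without pair 1, 7 without pair 2 and 15 without pair 3, and none changed sign in any setting. The count of 27 probe sets shifted 1.5-fold in all pairs was 101 with no dim filter, 4 at 2-fold, and 63 to 141 with only 2 pairs to satisfy. Against 11 called lists, 0 passed with an estimated correlation, 8 to 12 in the other settings with all pairs, and 3 to 10 when a pair or an array was left out. The amino acid, cell cycle and cholesterol lists passed in all 13 settings with the preset correlation and all 9 that left out a pair or an array. Dropping the pair block ended 1 list call, that of lung growth factors, and changed no other list call.

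None of the 79 genes followed through the settings and no called list changed sign with all pairs in the fit; the synthetase genes other than Cars1, Sars1 and Gars1 were not followed. Of the lists that did not pass, the fibroblast median was 0.0068 under quantile normalization and 0.010 under cyclic loess, and that of cyclic AMP signalling was -0.051 with no dim filter. When a pair or an array was left out, medians spanned 0 in the following lists, of which only the first was called. They ranged from -0.0086 to 0.12 for fatty acid synthesis, from -0.084 to 0.045 for type I genes, from -0.090 to 0.052 for actin and SRF targets, from -0.020 to 0.11 for cell junctions, from -0.059 to 0.091 for cyclic AMP signalling, and from -0.20 to 0.045 for inflammatory mediators. They ranged from -0.20 to 0.032 for the interferon response, from -0.069 to 0.14 for p53 targets, from -0.011 to 0.13 for heat shock, from -0.032 to 0.12 for hypoxia, from -0.11 to 0.011 for oxidative phosphorylation, from -0.28 to 0.084 for fibroblast and from -0.23 to 0.022 for mesothelial markers. Of the uncalled genes, Abca3 ranged from -0.37 to 0.029, Aqp5 from -0.52 to 0.20 and Pdpn from -0.13 to 0.068. Signal over background could not be judged singly, and genes such as Sftpa1, under the dim filter, were not tested.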

Other observations

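The tests of the type II share, of endoplasmic reticulum stress, of the module order, of the 3 cell shares for the cell cycle list, of the smooth muscle share for Fbn1, and of turned pairs for the count by size were chosen after the values had been seen. The genes that charge tRNA were not among the fixed lists. Beside Cars1, Sars1 and Gars1, 16 cytosolic aminoacyl-tRNA synthetase genes were measured, and 14 of them had positive log2 differences between strained and control cells, 6 of these in all 3 pairs. When adjusted over the 19 cytosolic genes alone, Wars1, Yars1, Aars1, Nars1 and Iars1 passed, at log2 differences of 0.39 ± 0.11 (SE), 0.47 ± 0.14, 0.34 ± 0.10, 0.39 ± 0.13 and 0.65 ± 0.23, the last positive in only 2 pairs. Kars1 and Qars1 were at -0.01 ± 0.11 and -0.03 ± 0.11.

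A hypothesis formed from Cars1, Sars1 and Gars1 was that cytosolic synthetase genes rose as a class and mitochondrial ones did not. Without these 3, the median log2 difference was 0.26 over 16 cytosolic genes and -0.18 over the 3 mitochondrial genes measured, a difference of 0.439 (exact permutation test over 969 arrangements of genes, 1-sided p = 0.0083). The result is consistent with the hypothesis, but 1 of the 3 mitochondrial genes, Tars2, was at 0.23 ± 0.21 (SE) and positive in all pairs, and the bootstrap interval of the difference, -0.015 to 0.573, included 0. The cytosolic median lay at percentile 100 of 10000 lists matched on mean signal. Genes are not independent replicates, so this describes the class in these 6 arrays.

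The amino acid and endoplasmic reticulum list rose in the test with the preset correlation, and its call was lost with an estimated one (adjusted p = 0.387). That estimate, 0.0012, lay below the preset 0.01, and this form of the test has few degrees of freedom with 3 pairs. A higher share of type II cells in the strained cultures is argued against, since surfactant and type II genes had a median log2 difference of -0.09 and the 13 measured amino acid members of the list one of 0.86, a gap of -0.952 (95% bootstrap interval -1.17 to -0.75). Bootstraps here and below drew genes, not cultures, so their intervals do not measure the spread between litters. For general endoplasmic reticulum stress, the values show only that the other members of the list did not rise as a set. These 13 members, Herpud1 among them, had a median of -0.06, which lay 0.487 below the bound set at 0.5 times the amino acid median (difference -0.487, interval -0.575 to -0.265). Herpud1 itself rose, and Ddit3, counted with the amino acid genes, also responds to such stress. The test therefore cannot exclude such stress as the cause. Fluidics module and scan order cannot be told apart from strain, because the control array came first in 3 of 3 pairs, and a direct response to strain stays open beside it.

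For the fall of the cell cycle list, a bootstrap over genes could not exclude a lower share of other cells in strained cultures. The cells weighed were fibroblasts, leukocytes, and smooth muscle cells with myofibroblasts. The median of the 13 fibroblast markers lay 0.389 above that of the cell cycle genes (95% bootstrap interval -0.03 to 0.59), and that of the 12 leukocyte markers lay 0.185 above it (interval -0.06 to 0.35). The 9 smooth muscle and myofibroblast markers came closest, with a median 0.0672 above it (interval -0.19 to 0.33), so all 3 intervals include 0. In pairs 1, 2 and 3 the medians were -0.14, -0.43 and -0.32 for the cell cycle list. They were -0.47, -0.38 and -0.02 for smooth muscle and -0.40, -0.35 and 0.12 for leukocyte markers. Pair 1, where these markers fell most, thus had the smallest cell cycle fall. This order goes against a lower share of these 2 cell types as the only cause, but rests on 3 pairs and was not tested. Whether strain slowed division of the epithelial cells themselves stays open beside these shares.

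The fall of Fbn1 was weighed against a lower share of fibroblasts, with a bound set before the test was run. The 12 other fibroblast markers had a median log2 difference of -0.0136 (95% bootstrap interval -0.30 to 0.16), above the bound of -0.38. Col1a1, abundant at a mean signal of 3873 in controls, was at 0.18 ± 0.09 (SE), with -0.05 ± 0.11 on its other probe set. The median of the markers argues against a loss of fibroblasts as the whole cause, while Col1a2 at -0.61 ± 0.15 went with Fbn1. A lower share of smooth muscle cells and myofibroblasts could not be excluded, since their 9 markers had a median of -0.346 and its interval, -0.489 to -0.0911, included the bound. A change of Fbn1 within the epithelial or the contaminating cells stays open, and its fall is kept as a hypothesis about strain, since module and scan order were not excluded.

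The 6 arrays allow too few other groupings to exclude chance at 0.05. With the pair block, 1 of the 10 splits into 3 and 3 gave as many called probe sets as the real one, which was the real one itself with 31, against a highest other count of 1. Only 4 of the 10 splits keep each pair apart. The others place both arrays of some pairs in 1 group, so their counts are not like the real one, and the count of 1 came from these. Each split with a turned pair gave 0 calls. For the count by size, 1 of 4 splits that keep each pair apart gave as many, again the real one with 27 against a highest other of 9. For called lists, 2 of the 10 splits gave as many, since the split with pair 3 turned, the pair on the separate chip lot, also gave 11. In that comparison of turned pairs, the amino acid list had an adjusted p of 0.0295 at its lowest and the cell cycle list 0.0011, against 6.61e-13 and 2.16e-07 in the real split. Of the called lists, those of leukocyte, smooth muscle and growth factor genes had lower p-values in a turned split than in the real one.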
